A study of Bos taurus with 33 samples.

How the data were processed

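Gene expression was measured in the endometrium of 33 heifers on Affymetrix bovine genome arrays, with 1 array per animal. The arrays come from 2 experiments. In the biopsy experiment, heifers received human interferon alpha (IFNA) in a lipid extrudate, the extrudate alone (placebo) or phosphate-buffered saline (PBS), and each animal gave 6 biopsies. In the pregnancy experiment, inseminated pregnant heifers and sham-inseminated cyclic heifers were sampled at slaughter on day 12, 15 or 18.

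The deposited table holds log2 expression values per probe set, made by the authors with RMA from the package affy per the submitters' processing notes, which give no versions. The values carry 2 decimals and run from 1.89 to 14.2. Sorted values matched closely within 4 sets of arrays (the 9 biopsy arrays and the arrays of each slaughter day) and differed between them: the largest SD of a sorted value was 0.334 over all 33 arrays and 0.05 to 0.067 within a set. The sets were therefore treated as normalised separately, an inference from the values that the submitters' notes do not state, with median log2 values of 6.64 for the biopsies, 6.85 for day 12, 6.49 for day 15 and 7.25 for day 18. Comparisons of IFNA, placebo and PBS, and of pregnant with cyclic animals on a day, stay within a set, whereas comparisons of cyclic animals between days cross sets. The number of arrays limits the precision: the median standard error of a log2 difference was 0.147 in the biopsy comparisons and 0.0906, 0.117 and 0.101 for pregnant against cyclic on days 12, 15 and 18.

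Of 24128 probe sets, 112 control probe sets were left out and 24016 were tested. Gene names came from the array's annotation: 13292 probe sets had 1 gene symbol, 86 had several and 10638 had none, and 13283 of the symbols were brought up to date by gene identifier in RefSeq. Where a gene had more than 1 probe set (2913 of 9155 genes), the probe set with the highest mean over all arrays stood for it. Where probe sets of a named gene disagree the text says so; C2, PLVAP and PECAM1 each have 1 other probe set that did not pass in the IFNA comparisons, and IRF7 and JUND each have 1 that passed the opposite way between days 12 and 15 in cyclic animals.

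The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, no covariates), on the 9 biopsy arrays, the 24 pregnancy arrays or, for the difference between IFNA and pregnancy effects, all 33 arrays. Tests were two-sided and Benjamini-Hochberg adjusted p-values below 0.05 counted as past the threshold. The change of the pregnancy effect between days, and the difference between the IFNA effect and a pregnancy effect, were tested as interaction terms. For these terms a larger effect means a positive difference and a smaller effect a negative one. A smaller effect can thus be a stronger fall or a change in the opposite direction. Overlaps were tested with Fisher's exact test, two-sided, against all probe sets tested. That test counts probe sets as independent and measures no spread between animals.

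The 24 gene lists covered the type I interferon response, antigen processing and MHC class I, MHC class II, chemokines and cytokines, complement, epithelial transport and secreted histotroph, steroid, oxytocin and prostaglandin receptors and enzymes, Wnt signalling, the cell cycle, extracellular matrix, immediate early and heat shock genes, and acute inflammation. The rest were markers of epithelium, ciliated epithelium, stroma, smooth muscle, endothelium, T and NK cells, B and plasma cells, macrophages and dendritic cells, neutrophils, mast cells, erythrocytes and platelets, and trophoblast. Each was tested with camera from limma at a preset inter-gene correlation of 0.01, with adjustment over 288 tests (24 lists in 12 comparisons). Of 76 list calls outside the comparisons between days of the cycle, 6 held with an estimated correlation: the type I interferon response in 5 comparisons, and antigen processing and MHC class I in the change of the pregnancy effect from day 12 to day 15.

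Named genes are the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the compared groups (no overlap asked for interaction terms, and symbols starting with LOC left out), the 4 list members with the largest change among those past the threshold, and a fixed set of interferon, steroid and histotroph genes. With 3 against 3 arrays, chance gives no overlap for 10% of genes. Values are given as log2 differences with the standard error from limma.

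The limma fit was tested on simulated data with the group sizes and spread of the real arrays, 24016 probe sets and 200 of them changed. Probe sets were drawn independently, so correlation between genes and uneven array quality were not simulated, and false call rates may differ in the real data. Overlaps, splits and permutation tests were not simulated. For IFNA against placebo the fit recovered 13.2% of changes of 0.5 log2, 71.2% of changes of 1 and 87.9% of changes of 2, and for placebo against PBS 5.88%, 57.6% and 92.4%. False calls were 7.32% of all calls for IFNA against placebo, 8.66% for IFNA against PBS, 6.2% for IFNA minus day 18, 6.04% and 9.14% for cyclic day 15 against 12 and 18 against 15, and 2.04% to 4.86% for the others, each in 1 simulated data set. For pregnant against cyclic, changes of 1 log2 were recovered in 95.5% of cases on day 12, 95.5% on day 15 and 93.9% on day 18.

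The alternatives tried were a filter that kept probe sets at or above their array's median in at least 3 arrays, quantile normalisation within each experiment, array weights, the trend and robust options of eBayes, the replicate number as a block, a fit on the compared groups alone, the mean of placebo and PBS as control, and each replicate left out in turn. After the values had been seen, 4 more were added: PBS as the control of IFNA in the interaction terms, the 3′ to 5′ signal difference of the GAPDH control probe sets as a covariate among the biopsies, leaving out the 3 biopsy arrays with the lowest such difference, and the dim probe set filter applied to the biopsy arrays for the interaction terms with IFNA. Figures and tests on groups of genes used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9; the limma functions that needed it used statmod 1.5.0.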

Results

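Endometrial gene expression was measured in 33 heifers, 1 array each. In the biopsy experiment, 3 heifers received IFNA in a lipid extrudate on day 14 of the cycle, 3 received the extrudate alone and 3 received PBS, and biopsies were taken on day 16. In the pregnancy experiment, pregnant and cyclic heifers were sampled on day 12 (5 and 5 animals), day 15 (3 and 3) and day 18 (4 and 4). The part of the uterine horn that was sampled differed between the days, so day and part cannot be separated. Values are log2 expression levels, and changes are log2 differences ± SE unless stated.

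RNA from the biopsies differed from that of the slaughter samples in its control signals. The 3′ probe set of GAPDH exceeded its 5′ probe set by 2.54 log2 on average in the 9 biopsy arrays (SD 0.93) and by 0.15 in the 24 slaughter arrays (SD 0.26). The means of the biopsy groups were close in this measure, at 2.38 with IFNA (SD 0.67), 2.58 with placebo (SD 1.44) and 2.67 with PBS (SD 0.94, n = 3 each). Arrays within a group were not: the placebo arrays ran from 1.03 to 3.87, the whole range of the biopsies. The same difference for EF1A was -0.38 in the biopsies and -1.82 at slaughter, whereas for actin it was lower in the biopsies (1.0) than at slaughter (2.23).

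**Figure D1:**
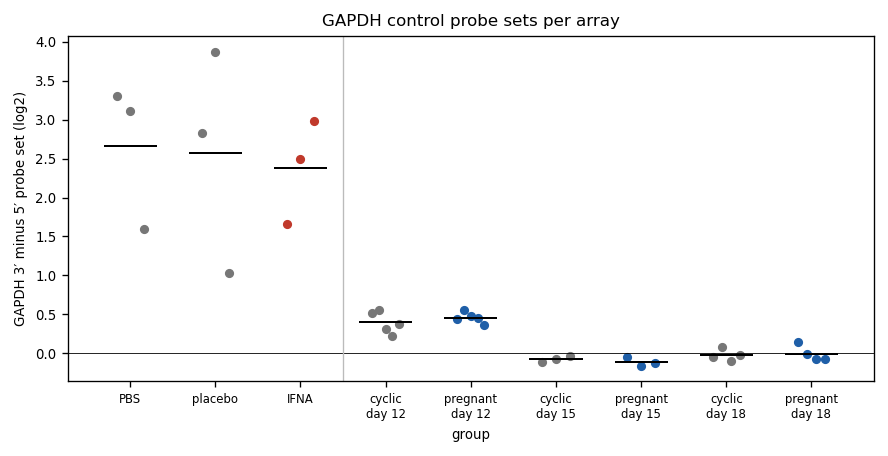
GAPDH 3′ minus 5′ control signal (log2, vertical axis) per array (points) in each group (horizontal axis), with the group mean as a line. Biopsy arrays lie between 1.03 and 3.87 and slaughter arrays between -0.16 and 0.56.

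The comparison of IFNA with placebo asks what the interferon does beyond its carrier. MX2, an antiviral GTPase, rose by 5.41 ± 0.249 log2 (42.5-fold; 11.09 against 5.68, n = 3 and 3). ISG15, a ubiquitin-like modifier induced by interferon, rose by 4.91 ± 0.227, and RSAD2, the antiviral protein viperin, by 4.22 ± 0.206 (adjusted p = 1.65e-05, 1.65e-05 and 2.01e-05 for these genes). IFI44L, IFI44, USP18, SAMD9, GBP4, PLAC8B and MX1 followed, with rises of 3.94 for IFI44L down to 3.04 for MX1. Of 47 measured genes of the type I interferon response, 36 rose, none fell and 11 did not pass; 42 rose when adjusted over the list alone. Their median change was 2.22 log2 (camera adjusted p = 2.4e-89, and 0.0123 with an estimated correlation).

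Complement genes and macrophage markers rose as well. In the complement list, 7 of 20 genes rose and none fell (10 adjusted over the list alone; median 0.82), among them C4A by 2.24 ± 0.266 and C2 by 1.64 ± 0.172, both components of the classical pathway. The list's adjusted p was 1.54e-10 and became 0.104 with an estimated correlation. Of 14 macrophage and dendritic cell markers, 3 rose (8 adjusted over the list alone): the C1q chains C1QB (1.84 ± 0.274) and C1QC (1.58 ± 0.247), which are also complement genes, and CSF1R (1.12 ± 0.188), the receptor for colony stimulating factor 1. Their median change was 1.01 (adjusted p = 3.25e-08, and 0.355 with an estimated correlation). Without IFNA animal 2, placebo animal 2 or placebo animal 3 all 3 calls ended. C1QC and CSF1R also lost theirs without IFNA animal 3, and CSF1R without IFNA animal 1, while the changes without any 1 animal stayed between 1.62 and 2.03 for C1QB, 1.40 and 1.70 for C1QC and 0.98 and 1.32 for CSF1R. In the fit on IFNA and placebo arrays alone CSF1R did not pass (adjusted p = 0.154). With the replicate number as a block none of the 3 passed (adjusted p = 0.0791, 0.0858 and 0.117).

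Among the other immune cell markers 1 gene passed. Neutrophil markers were lower as a list (median -0.21, adjusted p = 0.0362, and 0.424 with an estimated correlation), with 0 of 10 past the threshold in limma, 1 at an unadjusted p below 0.05 and 1 adjusted over the list alone. That list call ended in 3 of 6 fits with 1 animal left out and with the mean over probe sets (adjusted p = 0.0539). T and NK cell markers had 0 of 20 and mast cell markers 0 of 4 past it (4 and 1 at an unadjusted p below 0.05, 1 and 0 adjusted over the list alone), and of 8 B and plasma cell markers 1 rose, IGHM (1.60 ± 0.288). The IGHM call ended without any 1 of IFNA animals 1 to 3 and placebo animals 2 and 3 (1.37 to 1.95), after quantile normalisation (adjusted p = 0.0591) and in the fit on IFNA and placebo arrays alone (0.171).

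In antigen processing and MHC class I, 1 of 15 genes rose over all probe sets and 10 when adjusted over the list alone, with a median of 0.51 (adjusted p = 1.37e-10, and 0.355 with an estimated correlation); the gene was TAP1, a peptide transporter, at 1.53 ± 0.166. In MHC class II, BOLA-DMB, which helps load peptides, rose by 1.25 ± 0.142 and the other 9 genes did not pass (5 adjusted over the list alone; median 0.78, adjusted p = 0.000103, and 0.355 with an estimated correlation). Of 36 chemokines and cytokines, TNFSF13B, the B cell activating factor, rose by 2.03 ± 0.296 and CCL8, a monocyte attractant, by 2.03 ± 0.34 (4 adjusted over the list alone; list adjusted p = 0.113). The TNFSF13B call ended without IFNA animal 2 (range of change with 1 animal left out 1.77 to 2.39), and that of CCL8 without IFNA animal 2 or 3 or placebo animal 2 or 3 (1.73 to 2.35); in the fit on IFNA and placebo arrays alone neither passed (adjusted p = 0.0969 and 0.153). With the block TNFSF13B did not pass (0.0594). CXCL10, a lymphocyte attractant, was 2.95 ± 0.618 higher without passing (adjusted p = 0.0866).

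Other lists moved against placebo without a gene past the threshold in limma. Endothelial markers (median -0.16, adjusted p = 0.0128, and 0.666 with an estimated correlation) and extracellular matrix genes (-0.17, 0.0198, and 0.739 with an estimated correlation) were lower. Acute inflammation was higher (0.18, 0.0128, and 0.453 with an estimated correlation). Of 14, 38 and 25 genes, 3, 7 and 4 had an unadjusted p below 0.05, and 3, 0 and 2 passed adjusted over the list alone. Leaving out 1 animal at a time ended these list calls in 3, 2 and 4 of 6 fits, and with the mean over probe sets the first 2 did not pass (adjusted p = 0.0775 and 0.0561).

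No gene of the steroid, oxytocin and prostaglandin list passed. The oxytocin receptor OXTR differed by 0.51 ± 0.406, the oestrogen receptor ESR1 by -0.21 ± 0.176, the progesterone receptor PGR by -0.05 ± 0.174, and the uterine serpin SERPINA14 by 0.55 ± 0.897. Without any 1 animal these ran from 0.14 to 0.76, -0.35 to -0.09, -0.19 to 0.07 and 0.12 to 1.34. In the list of 24 steroid, oxytocin and prostaglandin genes limma called 0 past the threshold, with 1 at an unadjusted p below 0.05 (median -0.09). Among 35 genes of epithelial transport and histotroph only CTSS, a lysosomal protease, rose (0.66 ± 0.102; 2 adjusted over the list alone), and the list's median (-0.06) differed in sign from its mean (0.01) and its test (adjusted p = 0.931). The call of CTSS ended without any 1 of IFNA animals 1 to 3 and placebo animals 2 and 3 (0.62 to 0.73), and in the fit on IFNA and placebo arrays alone (adjusted p = 0.0928) and with the block (0.098).

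In total 208 of 24016 probe sets passed, 201 higher and 7 lower; by gene these were 102 higher and 2 lower. The 2 named genes that fell were KCNMA1, a potassium channel (-1.29 ± 0.22), and DHRS7, a short-chain dehydrogenase (-0.84 ± 0.141). Both calls ended without any 1 of IFNA animals 2 and 3 and placebo animals 1 to 3 (KCNMA1 -1.45 to -1.13, DHRS7 -0.98 to -0.74) and in the fit on IFNA and placebo arrays alone (adjusted p = 0.0543 and 0.117), and that of DHRS7 also with the block (0.121). Of 3 other probe sets for KCNMA1, 1 was also lower past the threshold. Without IFNA animal 2 the count was 136 (131 higher and 5 lower). The number of lower probe sets was 12 without IFNA animal 1, 2 without placebo animal 2 and 35 without placebo animal 3. The fit on IFNA and placebo arrays alone gave 124 (122 higher and 2 lower), array weights 323 (265 and 58), the mean of placebo and PBS as control 318 (264 and 54), and the GAPDH signal difference as a covariate 338 (299 and 39).

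Against PBS, which carried no extrudate, IFNA again raised interferon genes. MX2 rose by 5.54 ± 0.249, ISG15 by 5.07 ± 0.227 and RSAD2 by 4.18 ± 0.206 (n = 3 and 3), and 37 of 47 interferon response genes rose (44 adjusted over the list alone; median 2.19, adjusted p = 4.63e-86, and 0.0123 with an estimated correlation). NUPR1, a stress-induced nuclear protein, rose by 3.11 ± 0.362. The complement genes C2 (1.68 ± 0.172) and C4A (1.99 ± 0.266) were among 6 of 20 that rose (10 up and 1 down adjusted over the list alone; adjusted p = 3e-08, and 0.136 with an estimated correlation). The call of C4A ended without IFNA animal 2 or PBS animal 2 (1.85 to 2.07). In antigen processing and MHC class I 2 of 15 genes rose (10 adjusted over the list alone; median 0.51, adjusted p = 4.33e-09, and 0.355 with an estimated correlation). MHC class II had a median of 0.30 against PBS, with 1 of 10 genes higher (2 adjusted over the list alone; adjusted p = 0.0247, and 0.542 with an estimated correlation). The median over placebo was 0.78. The list call against PBS ended without IFNA animal 2 (adjusted p = 0.348) and with the mean over probe sets (0.0605). Acute inflammation had 0 of 25 past the threshold in limma (7 at an unadjusted p below 0.05, 1 adjusted over the list alone; median 0.24, adjusted p = 0.00503, and 0.404 with an estimated correlation).

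Markers of several cell types moved against PBS, the endothelial ones downwards. PLVAP, a protein of endothelial diaphragms, had -1.43 ± 0.176 (adjusted p = 0.00586), and PECAM1, an endothelial adhesion molecule, had -1.01 ± 0.153 (adjusted p = 0.0199). Those were the 2 of 14 endothelial markers past the threshold (6 lower adjusted over the list alone), and the list's median was -0.57 (adjusted p = 1.55e-07, and 0.369 with an estimated correlation). The call of PECAM1 ended without any 1 of IFNA animals 2 and 3 and PBS animals 1 to 3 (-1.08 to -0.89), and the 1 other probe set of each of the 2 genes did not pass. Of 14 macrophage markers 2 rose (8 adjusted over the list alone; median 0.63, adjusted p = 0.000336, and 0.508 with an estimated correlation). Epithelial markers were higher as a list (0.32, 0.00224, and 0.626 with an estimated correlation), and stromal (-0.27, 0.00354, and 0.392 with an estimated correlation) and neutrophil markers (-0.11, 0.00721, and 0.355 with an estimated correlation) were lower. In these 3 lists limma called 0 of 14, 12 and 10 genes, with 3, 3 and 4 at an unadjusted p below 0.05 and 0, 0 and 4 adjusted over the list alone. The list calls ended without IFNA animal 1 (adjusted p = 0.0724), PBS animal 1 (0.0524) and IFNA animal 3 (0.0668) in that order. The endothelial markers had a median of -0.40 in placebo against PBS and -0.16 in IFNA against placebo. EFNB3, an ephrin, changed by -1.40 ± 0.195, CD5L, a secreted macrophage protein, by -1.20 ± 0.158, and the cytokine IL33 by -1.05 ± 0.136. Their calls ended without PBS animal 1 or 2 for EFNB3 (-1.56 to -1.22), without PBS animal 3 for CD5L (-1.35 to -1.08) and without PBS animal 2 for IL33 (-1.20 to -0.94). Of the 38 extracellular matrix genes limma called 0 and 16 had an unadjusted p below 0.05, with a list median of -0.35 (adjusted p = 1.37e-06, and 0.453 with an estimated correlation).

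In total 207 probe sets passed against PBS, 171 higher and 36 lower (91 and 20 genes). The count was 110 without PBS animal 1 (103 higher and 7 lower), 110 without PBS animal 2 (106 and 4), 117 without IFNA animal 2 (106 and 11) and 124 without PBS animal 3 (112 and 12). It was 132 with the replicate number as a block (119 and 13) and 433 with array weights (288 and 145). The GAPDH covariate gave 231 higher and 78 lower, and leaving out the 3 biopsy arrays with the lowest GAPDH difference 152 and 23.

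Placebo against PBS asks whether the extrudate alone acts on the tissue. No gene passed: ISG15 differed by 0.15 ± 0.227, MX2 by 0.13 ± 0.249, OXTR by 0.11 ± 0.406 and SERPINA14 by 0.93 ± 0.897 (n = 3 and 3). Without any 1 animal these ran from -0.07 to 0.40, -0.05 to 0.35, -0.14 to 0.48 and 0.03 to 1.52. The limma count was 0 of 24016 probe sets, with 651 (2.71%) at an unadjusted p below 0.05. The 47 interferon response genes had a median of -0.10 (adjusted p = 0.116), with 0 past the threshold and 2 at an unadjusted p below 0.05. As groups, endothelial markers (median -0.40, adjusted p = 3.46e-06), macrophage markers (-0.26, 0.000746), extracellular matrix genes (-0.15, 0.000821), MHC class II (-0.39, 0.00594) and complement (-0.21, 0.0417) were lower, and cell cycle genes (0.17, 4.84e-05), immediate early genes (0.20, 0.000336) and epithelial markers (0.26, 0.00147) were higher; with an estimated correlation their adjusted p were 0.404, 0.532, 0.596, 0.451, 0.556, 0.382, 0.565 and 0.609. No member of these lists passed over all probe sets; at an unadjusted p below 0.05 limma gave 4, 0, 1, 1, 3, 4, 2 and 2 of them, and adjusted over each list alone 1, 0, 0, 0, 0, 0, 1 and 0 passed. Only the endothelial list call held whichever animal was left out. The others ended in 1 of 6 fits, extracellular matrix in 2 and complement in 3, with adjusted p up to 0.189 for macrophage markers, 0.0795 for extracellular matrix, 0.125 for MHC class II and 0.431 for complement. They reached 0.128 for the cell cycle, 0.0754 for immediate early genes and 0.775 for epithelial markers, and MHC class II did not pass with the mean over probe sets (0.0825).

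On day 12, pregnant and cyclic animals differed in 1 gene. LPL, the lipoprotein lipase that frees fatty acids from circulating lipids, had -1.62 ± 0.241 (adjusted p = 0.0241; 6.24 against 7.86, n = 5 and 5), between -1.83 and -1.42 with 1 animal left out. Interferon genes did not pass: IFI6, an interferon-induced mitochondrial protein, was 0.62 ± 0.164 higher (adjusted p = 0.409), MX1 0.57 ± 0.241 and ISG15 0.53 ± 0.292. The interferon response list had a median of 0.07 (adjusted p = 0.00164, and 0.689 with an estimated correlation), with 0 past the threshold over all probe sets, 1 adjusted over the list alone and 6 at an unadjusted p below 0.05 in limma. Its list call ended without pregnant animal 1 (adjusted p = 0.0837). Immediate early and heat shock genes had a median of 0.09 (adjusted p = 0.00274, and 0.494 with an estimated correlation). Of 27 genes limma called 0, with 0 at an unadjusted p below 0.05 and 0 adjusted over the list alone. That list call ended without pregnant animal 4 (adjusted p = 0.113). The count of 1 probe set (1597 at an unadjusted p below 0.05) became 0 without pregnant animal 1, 2, 4 or 5 or cyclic animal 3, 2 without cyclic animal 1, 2 or 5, and 3 without pregnant animal 3 or cyclic animal 4. It was 0 in the fit on day 12 arrays alone (LPL adjusted p = 0.208) and 2 after quantile normalisation.

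On day 15, interferon genes were strongly higher in pregnant animals. MX2 rose by 5.32 ± 0.312 (10.68 against 5.36, n = 3 and 3), ISG15 by 5.24 ± 0.378 and RSAD2 by 4.84 ± 0.328 (adjusted p = 9.66e-11, 1.92e-09 and 8.17e-10). Of the 47 interferon response genes 44 rose, none fell and 3 did not pass (45 adjusted over the list alone; median 2.15, adjusted p = 6.81e-97, and 0.000841 with an estimated correlation). PLET1, named for its expression in placenta, rose by 3.44 ± 0.40, CXCL10 by 2.95 ± 0.329 and CCL8 by 2.35 ± 0.214. In antigen processing and MHC class I 6 of 15 genes rose (10 adjusted over the list alone), including TAP1 (1.21 ± 0.165) and the proteasome activator PSME2 (0.79 ± 0.073); the list's adjusted p was 9.58e-10, and 0.0543 with an estimated correlation.

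Genes of the epithelium and its secretions also changed on day 15. In epithelial transport and histotroph 5 of 35 genes rose and 1 fell (7 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.00674, and 0.382 with an estimated correlation): FABP3, a fatty acid carrier, rose by 2.48 ± 0.449, the Wnt inhibitor DKK1 by 1.82 ± 0.419 and the glucose transporter SLC2A1 by 1.12 ± 0.166. The DKK1 call ended without cyclic animal 2 (1.35 to 2.10) and in the fit on day 15 arrays alone (adjusted p = 0.059). Of 14 epithelial markers 3 rose (3 adjusted over the list alone), including the junction proteins CLDN4 (1.32 ± 0.195) and CDH1 (0.64 ± 0.094); the list's median (-0.00) and mean (0.12) differed in sign (adjusted p = 0.395). In complement 4 genes rose and 1 fell of 20 (6 and 1 adjusted over the list alone; adjusted p = 0.00313, and 0.369 with an estimated correlation), with C4A at 1.76 ± 0.302 and C1R, a protease of the first component, at 1.05 ± 0.12. Of 36 chemokines and cytokines 3 rose (5 adjusted over the list alone; adjusted p = 0.0121, and 0.355 with an estimated correlation). SERPINA14 was 1.36 ± 0.456 higher and OXTR -0.49 ± 0.24, neither past the threshold (adjusted p = 0.0906 and 0.279); OXTR ran from -0.77 to -0.33 without any 1 animal.

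Among lower genes, EDN3, a vasoactive peptide of the endothelin family, changed by -1.0 ± 0.198 and ALG13, an enzyme of protein glycosylation, by -0.88 ± 0.14. FAP, a fibroblast protease, had -0.91 ± 0.19, a call that ended without pregnant animal 3 (-1.06 to -0.68); EDN3 and FAP did not pass in the fit on day 15 arrays alone (adjusted p = 0.061 and 0.0807). Of 14 endothelial markers 2 fell (5 adjusted over the list alone; median -0.47, adjusted p = 0.000846, and 0.561 with an estimated correlation). Macrophage markers had a median of 0.28 with 1 of 14 higher (1 adjusted over the list alone; adjusted p = 0.0213, and 0.596 with an estimated correlation), a list call that ended without cyclic animal 3 (0.225). In total 1218 probe sets passed, 661 higher and 557 lower (370 and 214 genes). The count was 601 without pregnant animal 1 (413 higher and 188 lower), 611 without cyclic animal 2 (399 and 212), 694 without pregnant animal 3 (467 and 227), 797 without cyclic animal 3 (482 and 315) and 465 in the fit on day 15 arrays alone (373 and 92).

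On day 18, PLET1 had the largest rise of any named gene, 6.94 ± 0.347 log2 (122.8-fold; 11.73 against 4.78, n = 4 and 4). MX2 rose by 5.57 ± 0.27, RSAD2 by 4.95 ± 0.284 and ISG15 by 4.90 ± 0.327 (adjusted p = 2.07e-12 for PLET1 and 1.46e-12, 2.38e-11 and 2.92e-10 for these). Of 47 interferon response genes 45 rose and 2 did not pass (45 adjusted over the list alone; median 2.44, adjusted p = 1.26e-64, and 0.00615 with an estimated correlation). UPK1B, a membrane protein of urothelium, rose by 4.00 ± 0.408, FABP3 by 4.00 ± 0.388, SERPINA14 by 3.32 ± 0.395 and SPP1, the adhesion protein osteopontin, by 1.93 ± 0.394. The last 3 belong to epithelial transport and histotroph, where 13 of 35 genes rose and 2 fell (15 and 3 adjusted over the list alone; median 0.33, adjusted p = 0.00274, and 0.355 with an estimated correlation).

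**Figure D2:**
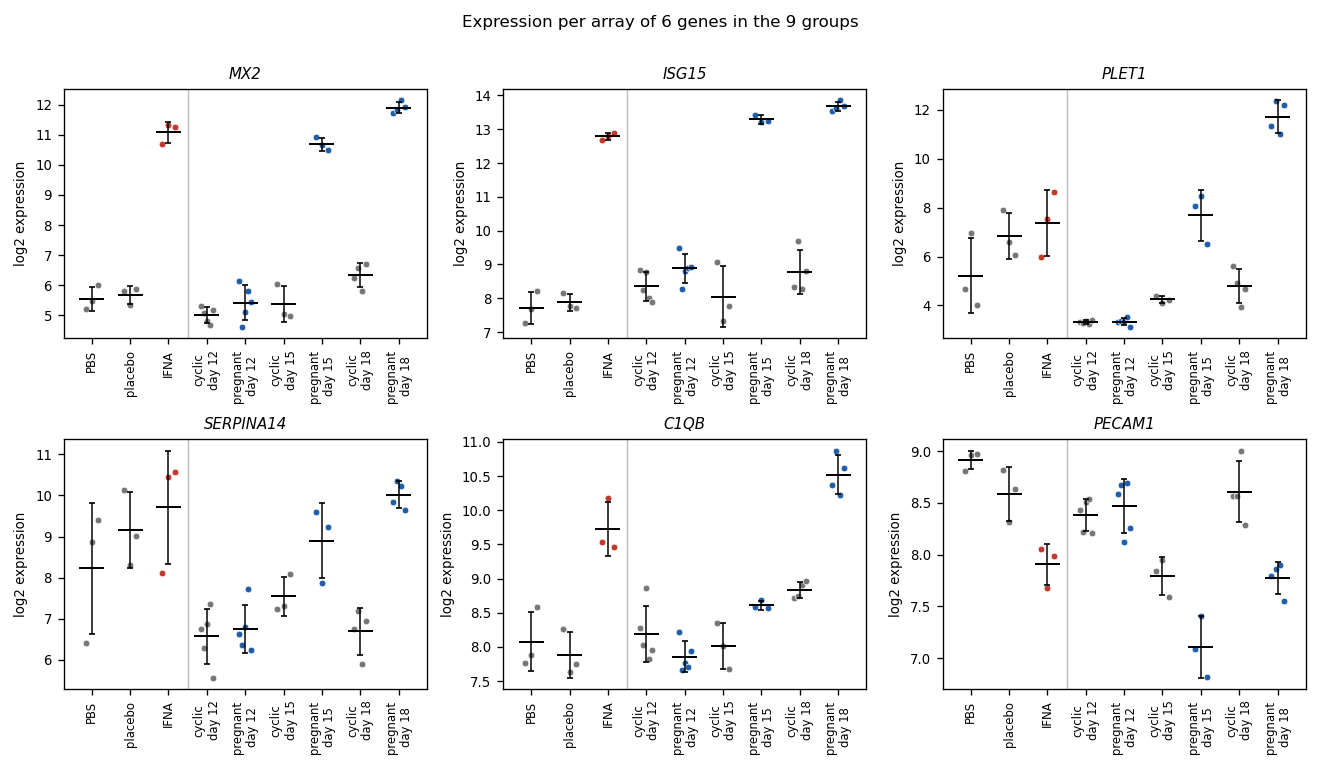
Log2 expression (vertical axis) of 6 genes per array (points) in the 9 groups (horizontal axis), with mean and SD as bars. MX2 and ISG15 are high with IFNA and on days 15 and 18 of pregnancy, whereas PLET1 averages 7.38 with IFNA and 11.73 on day 18 of pregnancy. The arrays left of the grey line, and those of each day to its right, appear to have been normalised separately. Levels are therefore directly comparable only within such a set.

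Genes of complement, chemokines, macrophages, acute inflammation and antigen presentation rose on day 18. In complement 12 of 20 genes rose and 2 fell (12 and 2 adjusted over the list alone; median 0.85, adjusted p = 1.4e-06, and 0.104 with an estimated correlation), with CFB, of the alternative pathway, at 2.36 ± 0.235 and C2 at 2.00 ± 0.118. Of 36 chemokines and cytokines 13 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.000127, and 0.104 with an estimated correlation), led by CXCL10 (3.41 ± 0.285), CCL8 (2.99 ± 0.185) and TNFSF13B (2.00 ± 0.176). Macrophage markers rose in 9 of 14 cases (11 adjusted over the list alone; median 0.97, adjusted p = 2.97e-07, and 0.175 with an estimated correlation), including C1QB (1.69 ± 0.185), the scavenger receptor MSR1 (1.44 ± 0.196) and the costimulatory CD86 (1.18 ± 0.109). In acute inflammation 11 of 25 genes rose (11 adjusted over the list alone; adjusted p = 4.95e-05, and 0.107 with an estimated correlation), with the pentraxin PTX3 at 3.58 ± 0.384 and the interleukin 1 antagonist IL1RN at 1.54 ± 0.161. In antigen processing and MHC class I 12 of 15 rose (12 adjusted over the list alone; adjusted p = 2.33e-09, and 0.0574 with an estimated correlation), and in MHC class II 3 of 10 (5 adjusted over the list alone; adjusted p = 0.0138, and 0.453 with an estimated correlation). The MHC class II list call ended without cyclic animal 1 (0.056).

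Single genes of hormone response and endothelial markers were lower on day 18. ESR1 had -0.70 ± 0.109, and AKR1B1, an aldo-keto reductase able to make prostaglandin F, had -0.66 ± 0.135; OXTR had -0.66 ± 0.208, a call that ended without pregnant animal 3 or 4 or cyclic animal 3 (-0.81 to -0.45) and in the fit on day 18 arrays alone (adjusted p = 0.0706). In their list of 24 genes 6 fell and 2 rose (6 and 3 adjusted over the list alone; adjusted p = 0.298). Of 14 endothelial markers 6 fell (7 adjusted over the list alone; median -0.37, adjusted p = 0.00147, and 0.579 with an estimated correlation), among them TIE1 (-0.92 ± 0.15) and PECAM1 (-0.83 ± 0.153). Of 4 ciliated epithelium markers 3 fell (4 adjusted over the list alone; median -0.82, adjusted p = 0.0383, and 0.588 with an estimated correlation), such as TPPP3 at -0.78 ± 0.201, and the list call ended in 3 of 8 fits with 1 animal left out (adjusted p up to 0.108). The largest falls were PTGR1, a prostaglandin reductase, with -1.51 ± 0.259, ISLR with -1.41 ± 0.248 and MPPED2 with -1.38 ± 0.176.

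In the cell cycle 4 of 34 genes rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.0534), led by CCNB2, a mitotic cyclin, at 2.14 ± 0.184. Of 27 immediate early and heat shock genes 8 rose (8 adjusted over the list alone; adjusted p = 0.0221, and 0.596 with an estimated correlation), with the stress factor ATF3 at 1.35 ± 0.222. The list call ended in 2 of 8 fits with 1 animal left out (adjusted p up to 0.141). Extracellular matrix genes split into 6 higher and 3 lower of 38 (8 and 4 adjusted over the list alone; adjusted p = 0.794), Wnt genes into 2 and 2 of 21 (2 and 2 adjusted over the list alone; adjusted p = 0.86), with a median of -0.05 and a mean of 0.08. Epithelial markers gave 4 higher and 1 lower of 14 (median -0.03, mean 0.05, adjusted p = 0.831) and stromal markers 1 and 2 of 12 (adjusted p = 0.459). T and NK cell markers gave 1 higher, CD69 (1.68 ± 0.195), and 1 lower, LCK (-0.75 ± 0.176), of 20. The other cell type lists gave 1 of 8 B and plasma cell markers higher, IGHM (1.28 ± 0.198), 2 of 10 neutrophil markers higher, led by S100A12 (2.41 ± 0.284), and 1 of 4 mast cell markers lower, FCER1A (-0.84 ± 0.153). Smooth muscle (12 markers) and erythrocyte and platelet markers (8) had 0 past the threshold in limma, with 2 and 1 at an unadjusted p below 0.05. Of 20 trophoblast markers none rose and SSLP1 had -1.05 ± 0.277 (adjusted p = 0.00995, and 0.0587 in the fit on day 18 arrays alone). It had -0.68 without pregnant animal 3 (adjusted p = 0.037). IFNT2, an interferon tau made by the conceptus, differed by 0.14 ± 0.126 (adjusted p = 0.521). In total 4562 probe sets passed, 2123 higher and 2439 lower (1150 and 953 genes).

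**Figure D3:**
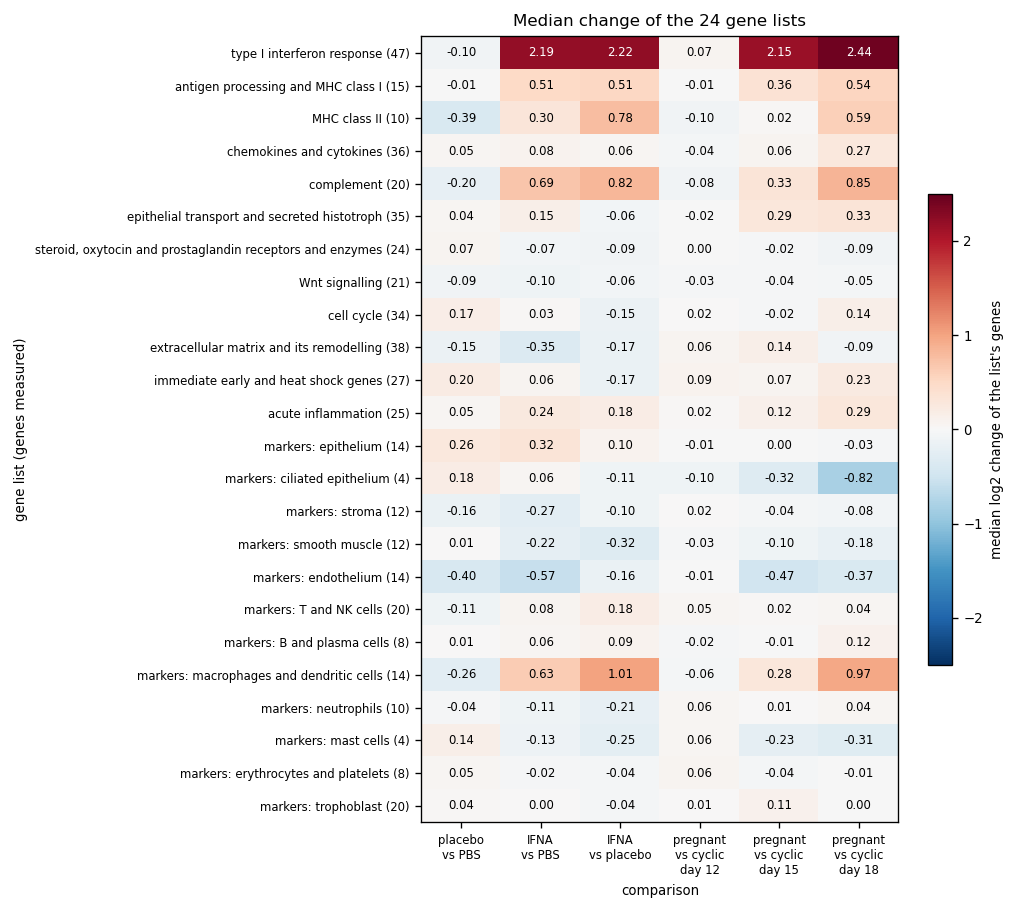
Median log2 change (colour and printed value) of the 24 gene lists (vertical axis, with the number of genes measured) in 6 comparisons (horizontal axis). The type I interferon response stands at 2.22 for IFNA against placebo, 0.07 on day 12, 2.15 on day 15 and 2.44 on day 18 of pregnancy.

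Testing the change of the pregnancy effect itself, the interferon genes were the clearest group from day 12 to day 15. The effect on MX2 was 4.90 ± 0.395 larger on day 15, that on ISG15 4.71 ± 0.478 and that on RSAD2 4.32 ± 0.415, and 41 of 47 interferon response genes had a larger effect (44 adjusted over the list alone; median 2.02, adjusted p = 2.09e-95, and 0.000841 with an estimated correlation). PLET1 (3.43 ± 0.507) and CXCL10 (3.19 ± 0.416) followed, and FAP had -1.21 ± 0.24. In antigen processing and MHC class I 6 of 15 genes had a larger effect (9 adjusted over the list alone; adjusted p = 1.37e-10, and 0.0417 with an estimated correlation). Complement (2 of 20 larger, 7 adjusted over the list alone; 0.000241, and 0.256 with an estimated correlation) and epithelial transport and histotroph (3 of 35, 6 adjusted over the list alone; 0.00517, and 0.378 with an estimated correlation) also had larger effects. So did chemokines and cytokines (3 of 36, 5 adjusted over the list alone; 0.0128, and 0.355 with an estimated correlation). Macrophage markers had a larger effect (median 0.35, adjusted p = 0.0043, and 0.508 with an estimated correlation) and endothelial markers a more negative one (-0.42, 0.00426, and 0.609 with an estimated correlation). The endothelial median was -0.007 on day 12 and -0.47 on day 15. Of 14 genes in each, 0 were past the threshold in limma (7 and 5 at an unadjusted p below 0.05, 4 and 2 adjusted over the list alone). The macrophage list call ended without cyclic day 15 animal 3 (adjusted p = 0.0615).

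The count from day 12 to day 15 was 477 probe sets, 328 with a larger and 149 with a smaller effect, meaning a positive and a negative difference. A smaller effect in this sense can be a fall on day 15, as for FAP. It was 282 without cyclic day 15 animal 2 (220 larger and 62 smaller) and 289 without pregnant day 15 animal 1 (218 and 71). The smaller ones were 83 without pregnant day 15 animal 3, 78 without pregnant day 12 animal 2 and 257 with the filter on dim probe sets.

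From day 15 to day 18 no interferon gene passed. The difference was 0.25 ± 0.413 for MX2, -0.34 ± 0.499 for ISG15 and 0.11 ± 0.434 for RSAD2, and limma called 0 of the 47 interferon response genes, with 1 adjusted over the list alone and 7 at an unadjusted p below 0.05 (median 0.15, adjusted p = 0.0534). Without any 1 animal the 3 ran from -0.09 to 0.44, -0.84 to 0.02 and -0.38 to 0.39, and after quantile normalisation they had 0.58, 0.13 and 0.47. Other genes had a larger effect on day 18: PLET1 by 3.50 ± 0.53, IDO1, which degrades tryptophan, by 2.08 ± 0.296, KRT17, a keratin, by 1.62 ± 0.254, C2 by 1.60 ± 0.18, OLR1, a scavenger receptor, by 1.60 ± 0.229 and BPI, a bactericidal protein, by 1.57 ± 0.232. UPK1B had 3.51 ± 0.623, a call that ended without pregnant day 15 animal 3 or cyclic day 15 animal 1 (2.95 to 3.84). OLR1 did not pass after quantile normalisation (adjusted p = 0.0621), and UPK1B, PLET1 and KRT17 did not pass in the fit on the arrays of days 15 and 18 alone (0.0711, 0.0814 and 0.0711). Macrophage markers had a larger effect as a group, with 2 of 14 past the threshold (8 adjusted over the list alone; median 0.62, adjusted p = 3e-08, and 0.14 with an estimated correlation). TENM3, a cell adhesion protein, had the lowest difference, -0.86 ± 0.108.

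More lists differed from day 15 to day 18. Larger effects came in complement (2 of 20, 7 adjusted over the list alone; adjusted p = 4.78e-05, and 0.173 with an estimated correlation) and the cell cycle (1 of 34, 1 adjusted over the list alone; 4.66e-05, and 0.553 with an estimated correlation). Acute inflammation had them too (1 of 25, 5 adjusted over the list alone; 0.000462, and 0.174 with an estimated correlation). MHC class II (median 0.55, adjusted p = 0.00274, and 0.369 with an estimated correlation) and chemokines and cytokines (0.18, 0.00745, and 0.355 with an estimated correlation) had larger effects. Trophoblast markers had smaller ones (-0.10, 0.0111, and 0.508 with an estimated correlation). In these last 3 limma called 0 of 10, 36 and 20 genes, with 4, 10 and 2 at an unadjusted p below 0.05 and 3, 3 and 0 adjusted over the list alone. The call for chemokines and cytokines ended without cyclic day 15 animal 1 (adjusted p = 0.0545), and that for trophoblast markers in 2 of 14 fits with 1 animal left out (up to 0.0724).

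The count from day 15 to day 18 was 50 probe sets, 40 larger and 10 smaller. It was 21 without pregnant day 15 animal 3 (18 and 3), 22 without cyclic day 15 animal 1 (18 and 4), 81 without pregnant day 18 animal 1 (61 and 20) and 23 in the fit on the arrays of both days alone (13 and 10). Without cyclic day 18 animal 1 the larger ones were 26. The smaller ones were 18 without pregnant day 18 animal 3, 6 without cyclic day 18 animal 4 and 4 without cyclic day 15 animal 3. They were 21 after quantile normalisation, 17 with array weights and 18 with the block.

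The comparison of the 2 experiments asks how far IFNA mimics a conceptus. Of the 201 probe sets that rose with IFNA, 157 (78.1%) also rose on day 15 of pregnancy and 197 (98%) on day 18, against 5.53 and 17.8 if the calls were independent (Fisher's exact p = 6.12e-210 and 2.5e-204). These p-values count probe sets as independent and measure no spread between animals. The shared ones were 157 of the 661 higher on day 15 and 197 of the 2123 higher on day 18, so most rises of pregnancy were not called with IFNA. In simulated data changes of 0.5 log2 were recovered in 13.2% of cases for IFNA against placebo, 63.2% on day 15 and 70.6% on day 18. The median change of the 201 was 1.56 with IFNA, 1.19 on day 15 and 1.69 on day 18, and 0.02 on day 12. MX2 rose by 5.41 with IFNA, 5.32 on day 15 and 5.57 on day 18, and ISG15 by 4.91, 5.24 and 4.90. Of the 7 lower probe sets 3 were among the 557 lower on day 15 and 4 among the 2439 lower on day 18 (Fisher's exact p = 0.000405 and 0.00288, with the same limit). KCNMA1 was among the 3 on day 15 (-0.93 ± 0.219), a call that ended without pregnant animal 1 or 3 or cyclic animal 3 (-1.03 to -0.81). Across all 24016 probe sets, which are not independent replicates, the changes with IFNA correlated with those on day 12, 15 and 18 at Pearson's r of 0.03, 0.43 and 0.55 (Spearman's rho 0.02, 0.08 and 0.27). Among the 208 probe sets past the threshold with IFNA r was 0.25, 0.82 and 0.93, and among those past it in neither comparison 0.01, 0.08 and 0.17. Days 15 and 18 of pregnancy shared 556 higher and 355 lower probe sets, and 0 that had changed on day 15 were past the threshold in the opposite direction on day 18.

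**Figure D4:**
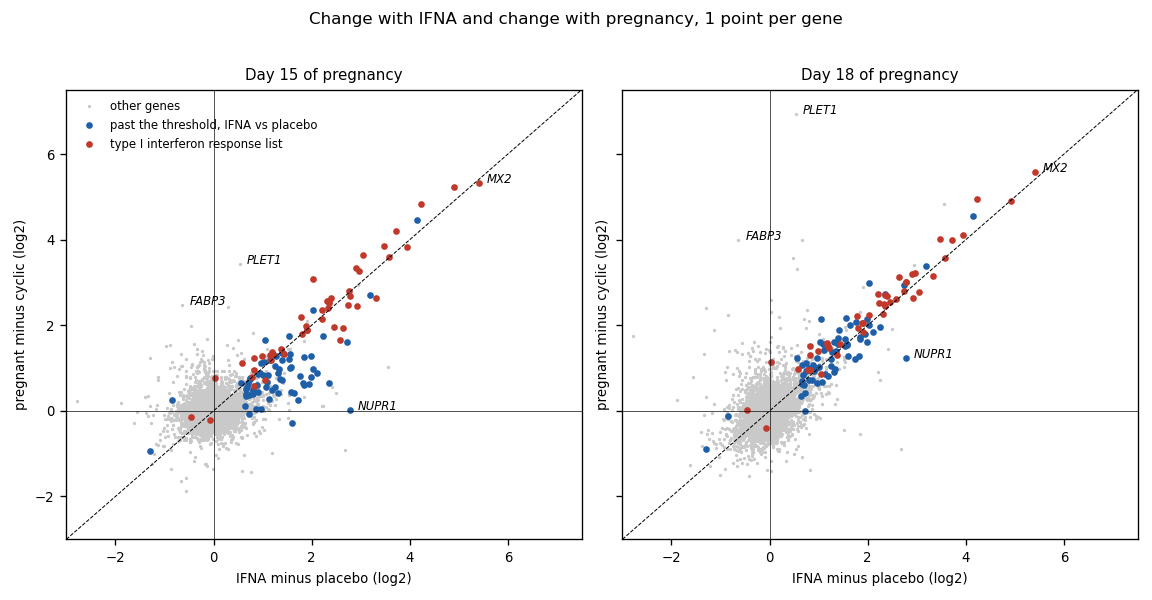
Log2 change with IFNA against placebo (horizontal axis) and with pregnancy (vertical axis) on day 15 (left) and day 18 (right), 1 point per gene, with equality as a dashed line. Interferon response genes (red, 1 probe set each) lie mostly near the line, MX2 at 5.41 with IFNA and 5.57 on day 18. PLET1 lies far above it on day 18 at 6.94.

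The calls shared with IFNA rested in part on single arrays and on the fit. The 3 shared lower probe sets of day 15 became 0 without pregnant animal 1 or 3 or cyclic animal 3, 1 without placebo animal 1 or 2 or cyclic animal 1, and 5 without IFNA animal 1 or placebo animal 3. The 4 of day 18 became 1 without placebo animal 2, 2 without IFNA animal 2 or placebo animal 1, and 15 without placebo animal 3. The higher probe sets shared with day 18 came to 130 without IFNA animal 2, and fits on the compared groups alone gave 98 higher probe sets shared with day 15 and 122 with day 18.

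Set against day 15 of pregnancy in 1 model, no interferon gene was called different between IFNA and pregnancy by the 1 probe set that stood for it. The difference between the effects was 0.09 ± 0.434 for MX2, -0.33 ± 0.502 for ISG15 and -0.62 ± 0.439 for RSAD2, and limma called 0 of 47 interferon response genes (0 adjusted over the list alone, 6 at an unadjusted p below 0.05; median -0.12, adjusted p = 0.298). Without any 1 animal the 3 ran from -0.25 to 0.29, -0.83 to 0.03 and -1.11 to -0.34, and after quantile normalisation MX2 had 0.21 and ISG15 -0.13. Some probe sets of interferon genes, picked for not passing with IFNA, changed less there than on day 15. Those of RTP4 had 0.13 and 0.35 with IFNA and 3.14 and 2.99 on day 15. Those of PARP12 had 0.02 and 0.36 against 1.8 and 1.86, and that of IRF7 0.19 against 1.57. Others so picked lay closer, such as that of ZNFX1 (2.37 and 2.91). IFNA had the larger effect on NUPR1 (2.77 ± 0.472), IGHM (1.89 ± 0.363) and C2 (1.23 ± 0.211), and the smaller effect on NTS, the peptide neurotensin (-2.07 ± 0.367), and SLC25A5, a mitochondrial nucleotide carrier (-1.72 ± 0.284). ALG13 differed by 1.17 ± 0.211. In the fit on the 12 arrays alone these 6 genes did not pass (adjusted p = 0.291, 0.22, 0.222, 0.264, 0.0538 and 0.22 in that order). Macrophage markers had a median difference of 0.75 (0 past the threshold in limma, 9 adjusted over the list alone, 9 at an unadjusted p below 0.05; list adjusted p = 9.83e-05, and 0.369 with an estimated correlation), and complement genes 0.46 (2 of 20 larger, 7 adjusted over the list alone; 9.62e-05, and 0.172 with an estimated correlation). MHC class II had 0.70 (1 of 10 larger, 5 adjusted over the list alone; 0.00174, and 0.355 with an estimated correlation). Lists also went the other way: extracellular matrix (-0.30, 0.00204, and 0.588 with an estimated correlation) and immediate early and heat shock genes (-0.21, 0.00313, and 0.553 with an estimated correlation). Trophoblast markers did so as well (-0.14, 0.0121, and 0.481 with an estimated correlation). In these 3 limma called 0 of 38, 27 and 20 genes, with 9, 6 and 1 at an unadjusted p below 0.05 and 0, 2 and 0 adjusted over the list alone. Of 10 neutrophil markers 1 had a smaller effect (1 adjusted over the list alone; -0.19, 0.0175, and 0.356 with an estimated correlation). With 1 animal left out the list calls ended in 1 of 12 fits for immediate early genes (adjusted p = 0.0602), 2 for trophoblast markers (up to 0.0537) and 2 for neutrophil markers (up to 0.0591). The count was 89 probe sets, 45 larger and 44 smaller with IFNA, and the GAPDH control signals differed between the biopsies and the slaughter arrays by the amounts given above.

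That count depended on the arrays. It was 17 without IFNA animal 2, 26, 40 and 53 without cyclic day 15 animal 2, 3 and 1, 33 and 34 without pregnant day 15 animal 1 and 3, 144 and 193 without IFNA animal 3 and 1, and 150 and 414 without placebo animal 3 and 2. It was 2 in the fit on the 12 arrays alone, 1026 with array weights, 228 with the GAPDH covariate and 208 without the 3 biopsy arrays with the lowest GAPDH difference. The 44 smaller ones were 27 without placebo animal 1.

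It also depended on the control. With PBS in place of placebo, a test added after the values had been seen, 16 probe sets differed from day 15, 6 larger and 10 smaller with IFNA. NUPR1 (3.10 ± 0.472) and C2 (1.27 ± 0.211) still passed, whereas IGHM (1.61 ± 0.363), ALG13 (0.96 ± 0.211), NTS (-1.14 ± 0.367) and SLC25A5 (-1.07 ± 0.284) did not (adjusted p = 0.116, 0.103, 0.273 and 0.189). Of the lists, macrophage markers had a median difference of 0.34 (adjusted p = 0.0423, and 0.666 with an estimated correlation), and complement 0.36 (0.00587, and 0.378 with an estimated correlation). MHC class II had 0.34 (0.0699), immediate early and heat shock genes -0.04 (0.452) and trophoblast markers -0.10 (0.0646). Extracellular matrix had -0.47 (3.94e-08, and 0.355 with an estimated correlation), and neutrophil markers -0.15 (0.000612, and 0.12 with an estimated correlation). Stromal markers had -0.24 (0.0111, and 0.378 with an estimated correlation) and the interferon response -0.17 (0.0476, and 0.787 with an estimated correlation).

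Set against day 18, the change with IFNA over placebo was lower for PLET1, FABP3 and S100A12. The difference was -6.41 ± 0.805 for PLET1, -4.64 ± 0.708 for FABP3, -3.72 ± 0.447 for S100A12, a calcium-binding protein of neutrophils, -3.03 ± 0.423 for FGFBP1, a carrier of fibroblast growth factors, and -2.66 ± 0.505 for AGR2, a protein disulphide isomerase of secretory cells (adjusted p = 6.26e-05, 0.000882, 3.52e-05, 0.000253 and 0.00683). Relative to the median of the biopsy arrays, PLET1 stood at 0.74 with IFNA, 0.21 with placebo and -1.42 with PBS. The others were lower with IFNA than with placebo, none past the threshold. FABP3 stood at 1.82 against 2.46, S100A12 at 0.98 against 2.28, FGFBP1 at -1.48 against -0.35 and AGR2 at 3.1 against 4.43. With PBS these stood at 1.6, 2.69, -1.41 and 3.41 in that order. ATF3 (-1.79 ± 0.338) and CCNB2 (-1.45 ± 0.31) also differed. The fit on the 14 arrays alone left FABP3, FGFBP1, ATF3 and CCNB2 short of the threshold (adjusted p = 0.0669, 0.0543, 0.139 and 0.254). UPK1B (-3.35 ± 0.677) lost its call without IFNA animal 2 (-3.89 to -2.79) and in the fit on the 14 arrays alone (adjusted p = 0.152), and PTX3 (-3.09 ± 0.653) without placebo animal 1 (-3.30 to -2.81). SERPINA14 had -2.77 ± 0.855 without passing (adjusted p = 0.115). For interferon genes MX2 had -0.16 ± 0.406 and ISG15 0.01 ± 0.47. Without any 1 animal they ran from -0.33 to 0.04 and -0.30 to 0.18, and after quantile normalisation they had -0.37 and -0.26. Of the 47 genes 1 differed, IFIT2 with -1.12 ± 0.246 (1 adjusted over the list alone; median -0.22, adjusted p = 0.00311, and 0.671 with an estimated correlation), a call that ended without placebo animal 1 (-1.22 to -0.99) and in the fit on the 14 arrays alone (adjusted p = 0.0855).

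Of 35 genes of epithelial transport and histotroph 1 had a smaller effect with IFNA (1 larger and 2 smaller adjusted over the list alone; adjusted p = 0.00398, and 0.355 with an estimated correlation). Chemokines and cytokines had 0 of 36 past the threshold in limma (6 at an unadjusted p below 0.05, 2 smaller adjusted over the list alone; median -0.14, adjusted p = 0.0359, and 0.453 with an estimated correlation). A smaller effect was called for 2 of 25 genes of acute inflammation (2 adjusted over the list alone; 0.0209, and 0.392 with an estimated correlation) and 2 of 10 neutrophil markers (2 adjusted over the list alone; 0.0121, and 0.355 with an estimated correlation). With 1 animal left out the list calls ended in 8 of 14 fits for chemokines and cytokines (adjusted p up to 0.197), 4 for acute inflammation (up to 0.172) and 2 for the interferon response (up to 0.107).

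As groups, genes of the cell cycle (median -0.19, adjusted p = 0.000612, and 0.563 with an estimated correlation) and immediate early and heat shock genes (-0.27, 5.42e-05, and 0.381 with an estimated correlation) had a lower change with IFNA than on day 18, with 1 of 34 and 1 of 27 genes past the threshold (8 and 5 adjusted over the list alone). Over placebo the changes differed in direction: the cell cycle median was -0.147 with IFNA against placebo and 0.138 on day 18. Immediate early and heat shock genes had -0.17 with IFNA against placebo and were higher as a list on day 18. Over PBS the medians with IFNA were positive, 0.03 for the cell cycle and 0.06 for immediate early genes. Placebo against PBS had 0.17 and 0.20, so the direction with IFNA depended on the control. The count was 262 probe sets, 89 larger and 173 smaller with IFNA. It was 106 and 625 without placebo animal 1 and 3, 490 without placebo animal 2, 124 without IFNA animal 2, 135 without cyclic day 18 animal 2, and 166 and 478 without pregnant day 18 animal 2 and 1. It was 19 in the fit on the 14 arrays alone, 1269 with array weights, 477 with the GAPDH covariate and 480 without the 3 biopsy arrays with the lowest GAPDH difference. The 89 larger ones were 53 without pregnant day 18 animal 3, and the 173 smaller ones were 115 without cyclic day 18 animal 3.

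With PBS in place of placebo, also added after the values had been seen, 108 probe sets differed from day 18, 30 larger and 78 smaller. PLET1 (-4.78 ± 0.805), FABP3 (-3.78 ± 0.708), S100A12 (-4.12 ± 0.447), FGFBP1 (-1.97 ± 0.423) and IFIT2 (-1.07 ± 0.246) still passed (adjusted p = 0.00471, 0.0129, 1.57e-05, 0.0321 and 0.0449). AGR2 (-1.64 ± 0.505), UPK1B (-2.43 ± 0.677), PTX3 (-1.64 ± 0.653), ATF3 (-0.77 ± 0.338) and CCNB2 (-0.91 ± 0.31) did not (0.172, 0.125, 0.319, 0.372 and 0.245). The lists of the cell cycle (-0.15, 0.142), immediate early and heat shock genes (-0.14, 0.0752) and chemokines and cytokines (-0.22, 0.0527) no longer passed. The interferon response (-0.30, 4.38e-05, and 0.538 with an estimated correlation), and epithelial transport (-0.21, 0.0257, and 0.459 with an estimated correlation) still did. So did acute inflammation (-0.20, 0.0369, and 0.459 with an estimated correlation) and neutrophil markers (-0.34, 0.000546, and 0.116 with an estimated correlation). Extracellular matrix (-0.37, 4.38e-05, and 0.459 with an estimated correlation), epithelial markers (0.57, 0.00515, and 0.557 with an estimated correlation) and ciliated epithelium markers (0.91, 0.0225, and 0.534 with an estimated correlation) passed only with PBS.

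Cyclic animals on different days show the course of the cycle without a conceptus, but their arrays appeared to be normalised apart and came from different parts of the horn. The median of all probe sets shifted by -0.21 log2 from day 12 to day 15 and by 0.66 from day 15 to day 18, and changes are given relative to it. From day 12 to day 15 (n = 5 and 3), CA2, a carbonic anhydrase, rose by 3.90 relative to the shift, GPLD1, a phospholipase, by 3.42 and S100A12 by 3.00, whereas CNGA1 had -3.36, the serum amyloid SAA3 -3.34 and PSAT1, an enzyme of serine synthesis, -3.09. ESR1 had -0.69 (-0.67 after quantile normalisation) and SPP1 -1.14 (-1.26). As deposited 13872 probe sets passed, 21.4% of them higher; after quantile normalisation 12170 passed, 52.9% higher, and 34 of those called as deposited passed in the opposite direction; with the filter on dim probe sets 8495 passed.

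From day 15 to day 18 (n = 3 and 4), OXTR, which carries the oxytocin signal for prostaglandin release, rose by 1.79 relative to the shift (1.73 after quantile normalisation, adjusted p = 6.68e-06) and ESR1 by 1.10 (0.95). BAZ2B rose by 2.06 and the thioesterase ACOT4 by 1.82. CRIPTO, a growth factor co-receptor, had -3.55, the hormone-processing protease PCSK1 -1.89, and SERPINA14 -1.51, which passed after quantile normalisation (adjusted p = 0.00423) and not as deposited (0.0691). PGR was 0.60 higher as deposited but -0.06 relative to the shift, and -0.11 after quantile normalisation (adjusted p = 0.543). Epithelial transport and histotroph genes were lower than other genes (camera adjusted p = 1.75e-06, and 0.104 with an estimated correlation) although their median (0.63) and mean (0.40) as deposited were positive. As deposited 20136 probe sets passed, 94.9% of them higher; after quantile normalisation 9563 passed, 51.4% higher, and 2183 of those called as deposited passed in the opposite direction; with the filter on dim probe sets 11700 passed.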

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

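Of the tests in this part, those of RNA quality, probe set brightness, conceptus RNA and the share of the main cell type were chosen after the results had been seen.

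Some genes had 1 probe set that rose with IFNA and another that rose on day 18 of pregnancy but did not pass with IFNA. There were 30 such probe sets in 23 genes, with a median change of 0.59 with IFNA and 1.08 on day 18, from RTP4 (0.13 and 2.57) and PARP12 (0.02 and 1.77) to ZNFX1 (2.37 and 2.88), so some were clearly higher with IFNA without passing. Degraded biopsy RNA, read best at its 3′ end, is a candidate explanation. Relative to slaughter samples the 30 were dimmer in untreated biopsies than the 54 that rose (medians -0.32 and 0.37, difference -0.68, permutation p = 0.0001, the smallest that 10000 permutations can give). The GAPDH control signals pointed the same way while those of actin did not. The dimness cannot decide this: the 30 were picked for not passing in the biopsies, so probe sets weak there for any reason fall among them. The position of a probe set along its gene was not used, and the permutations treat probe sets of the same gene as independent. Low brightness as such cannot be told apart from degraded RNA: in cyclic day 15 samples the medians differed by -0.47 (permutation p = 0.4562), and in a set of 12, chosen after the values were seen for an IFNA effect below 0.5 of that on day 18, both differences were larger (-1.18, permutation p = 0.0001, and -1.99, permutation p = 0.0069). Splice forms that differ between the treatments stay open, untested.

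In 93 genes the rise on day 18 of pregnancy exceeded the response to IFNA over placebo. Over PBS 78 probe sets had the smaller effect with IFNA, against 173 over placebo. The 93 were picked on the change over placebo, so genes with high values in the placebo arrays fall among them. In most of the 93 placebo stood above PBS, although limma called 0 probe sets between placebo and PBS. Conceptus RNA in the samples is argued against by the trophoblast markers, of which 0 of 20 rose in limma (2 at an unadjusted p below 0.05) with a median of -0.0025. Levels already raised in untreated biopsies could contribute, since the PBS biopsies stood at a median of 0.89 of the day 18 rise (95% bootstrap interval 0.71 to 1.16; at least 0.5 in 60 of 93 genes). This was not particular to these genes: 1057 other genes higher on day 18 had 0.79 (difference 0.1, permutation p = 0.5206), the comparison crosses arrays that appear to have been normalised separately, and the 11 genes that rose by at least 2 log2 had only 0.27. Dose, duration and other signals of the conceptus stay open, untested.

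Macrophage markers were higher with IFNA and on day 18. A loss of the main cell type alone would raise the markers of all other types alike. Macrophage markers moved apart from endothelial markers by 1.16 with IFNA (permutation p = 0.0001, the smallest possible) and 1.34 on day 18 (permutation p = 0.0003). This pair of lists was chosen after the results had been seen, and the permutations shuffle genes and not animals. The gap therefore cannot decide whether the shares of cell types changed. More macrophages in the tissue is a candidate explanation: the 11 markers outside the complement list had medians of 0.66 with IFNA (0.35 to 0.94 with 1 animal left out, 1 past the threshold) and 0.54 on day 18 (0.44 to 0.62, 6 past). Induction of these genes in resident cells stays open, since bulk tissue does not separate it.

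Of 208 groups of 4 or 5 arrays examined for named genes, 11 had an array apart from the others, and chance alone gives about 1 in 20. In cyclic day 18 animal 3 ESR1 stood at 6.41 (others 5.97 to 6.0), LCK at 8.56 (7.99 to 8.04) and S100A8 at 6.64 (5.86 to 5.95), and in cyclic day 18 animal 2 RSAD2 at 8.7 (7.89 to 7.94). In pregnant day 18 animal 2 NDC80 stood at 4.65 (4.03 to 4.11), IL1RN at 8.2 (7.38 to 7.46) and TEKT1 at 6.66 (7.81 to 7.97), in animal 1 IFI44 at 9.62 (10.77 to 10.99) and FZD10 at 5.11 (5.48 to 5.54), and in animal 3 SAMD9 at 10.57 (9.67 to 9.8) and SSLP1 at 8.2 (9.61 to 9.81).

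The effect of pregnancy differed between days by the interaction tests, for 477 probe sets from day 12 to 15 and 50 from day 15 to 18. Among 100 splits of the arrays within days, 7, the real one among them, gave at least as many in each case (highest other 634 and 1903). All 7 kept a pair of groups intact and so carry the pregnancy effect of that day. Their share therefore neither excludes chance nor points to it. The splits with none intact, 88 and 82 in number, gave at most 3. The structure of the samples that these high counts point to is thus the pregnancy effect of the groups left intact.

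For the other comparisons, chance was judged by a share of splits as large below 0.05, not adjusted over the comparisons. By that rule it can be excluded for day 18 of pregnancy (4562 probe sets, highest other 5), where only the real one of 35 splits was as large. That is the smallest share the group sizes allow. The same holds for cyclic day 15 against 12 (13872, 1 of 56 splits, highest other 5367) and cyclic day 18 against 15 (20136, 1 of 35, highest other 16979). In these last 2 the real split is also the split by apparent normalisation set, so excluding chance there says nothing about the cycle. It is not excluded for day 12 (1 probe set; 17 of 100 splits as large; highest other 7), nor for the differences between IFNA and pregnancy on day 15 (89; 18 of 100; 1311) and day 18 (262; 9 of 100; 2465). Of these 18 and 9 splits, 13 and 4 kept a pair of groups intact and so carry its effect, and the splits with none intact gave at most 534 and 717, also above the real counts; what structure of the samples those point to was not tested. With 10 splits a share under 0.05 cannot be reached: IFNA against placebo gave 208 (1 of 10; highest other 32), IFNA against PBS 207 (1 of 10; 0), day 15 of pregnancy 1218 (1 of 10; 1) and placebo against PBS 0 (10 of 10; 4).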

How the results depend on the processing

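The GAPDH covariate, the analysis without the 3 biopsy arrays with the lowest GAPDH difference, the filter on the biopsy arrays (97 and 254 for IFNA minus day 15 and day 18 of pregnancy) and PBS as the control of IFNA (16 and 108 for these) were chosen after seeing the data; the other alternatives were planned. The total counts of probe sets kept within 1.5 times their value, except as follows; the cause was not tested unless stated. Array weights gave 323 (IFNA against placebo), 433 (IFNA against PBS), 1026 and 1269 (IFNA minus day 15 and day 18 of pregnancy). The fit on the compared groups alone, which estimates the spread from fewer arrays, gave 124 (IFNA against placebo), 0 (day 12), 465 (day 15), 23 (day 15 to 18), 2 and 19 (IFNA minus day 15 and day 18), and shared probe sets of 98 higher and 1 lower (day 15) and 122 higher and 1 lower (day 18). Quantile normalisation gave 2 (day 12) and 9563 (cyclic day 18 against 15), where it removes the shift of the median, and PGR there turned to -0.11. The filter on dim probe sets tested fewer and gave 8495 and 11700 (cyclic day 15 against 12 and 18 against 15), and 6 and 10 shared lower probe sets on days 15 and 18; array weights gave 13 and 28 of these. The mean of placebo and PBS as control gave 318, and the replicate number as a block 132 (IFNA against PBS); these numbers do not pair the animals, as same-number deviations correlated at -0.337 to 0.368. The GAPDH covariate gave 338 (IFNA against placebo), 228 and 477 (IFNA minus day 15 and day 18), and without the 3 arrays placebo against PBS gave 1 and the last 2 gave 208 and 480. With 1 animal left out, which lowers the number of arrays, counts ran from 136 to 257 (IFNA against placebo), 110 to 232 (IFNA against PBS), 0 to 3 (day 12), 601 to 1122 (day 15), 3419 to 4908 (day 18), 282 to 476 (day 12 to 15), 21 to 81 (day 15 to 18), 17 to 414 and 106 to 625 (IFNA minus day 15 and day 18), and shared probe sets from 0 to 5 lower (day 15), 130 to 228 higher and 1 to 15 lower (day 18). The arrays that moved a total by over 1.5 times are named in the report. There were 347 results of named genes past the threshold, where a gene counts once for each comparison. Of these, 330 kept direction and side with quantile normalisation, 305 with the block and 244 in the fit on the compared groups alone. Of 76 list calls, 76 held with the block, 71 with the mean over probe sets, 6 with an estimated correlation, and 46 whichever animal was left out. Median standard errors were 0.147 in the biopsies, so changes below 1 log2 there were often missed in simulated data.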
